A study of Homo sapiens with 3 samples.

How the data were processed

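Gene expression was measured with 1-colour Affymetrix whole-transcript microarrays in A549, an established human lung cancer cell line. Cells were transfected with a control siRNA (siNC), an siRNA against TAZ (siTAZ) or an siRNA against YAP (siYAP), and total RNA was taken after 48 h. Each group had 1 array, so the series holds 3 arrays and no replicate. Labelled cDNA was made from 500 ng of total RNA, per the labels' protocols.

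The deposited table gives a value for each of 53617 probe sets on each array. The authors summarised the arrays with RMA (background correction, quantile normalization and a median polish over the probes of a probe set), per the submitters' processing notes; the RMA version, the annotation and the genome build are not given in the sources used here. The scale of the values deposited by the authors is not named, and was read as log2 because they ran from 0.97 to 13.5 with near-equal quartiles on the 3 arrays, as RMA writes. Quantile normalization removes any difference in total RNA per cell, so every value is relative to the other probe sets of its array. The scanner files and the number of probes per probe set were not used here.

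Gene symbols came from the platform's annotation table, in which 16098 probe sets had 1 symbol, 0 had several and the other 37519 were unnamed. All 16098 Entrez identifiers matched the RefSeq gene table of assembly GRCh38.p14, and the update changed 0 symbols. No coordinates are printed because the build behind the array's annotation is not named. The 16098 probe sets stood for 14884 genes, of which 779 had over 1 probe set; the probe set with the highest mean over the 3 arrays represented its gene. Genes were kept when that mean was at or above the median over all probe sets (4.27 on the log2 scale), which left 10768 genes, 9542 of them protein coding.

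With 1 array per group no test across replicates was possible, and no p-value or standard error is given. The difference between 2 arrays is the difference of their log2 values, and a fold is 2 raised to that difference. Genes were counted at 2-fold and at 1.5-fold. For 34 gene lists, 32 of which kept at least 3 members, the median difference was placed as a percentile among 10000 random lists of the same size matched on mean level in 10 bins. A list was said to stand apart at or under percentile 2.5 or at or over 97.5. This describes these 3 arrays, and treats the members of a list as if they were drawn independently. Over 32 lists, about 5% would stand apart in a comparison by the definition of the bounds if no differences were tied. However, 48.5% to 53.9% of the kept genes had a difference of exactly 0, so random medians pile up at 0 and this share need not hold. For some lists, such as the type I interferon list, both bounds were 0, so a median slightly off 0 can stand apart. The histone list had no named member, and the fibroblast marker list kept 2, too few for a percentile. The lists held 682 distinct genes, of which 417 were named on the array and 387 were kept, and 5 genes were on over 1 list. They were written from general knowledge of each pathway, not from these arrays.

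The comparisons with siNC share the control array. Their agreement is therefore given beside 100 simulations of 3 unchanged arrays with independent normal noise of SD 0.0903 per array, taken from the spread of siYAP minus siTAZ across genes. That spread includes real differences between the knockdowns as well as noise.

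The following choices were made before the data were examined: the thresholds, filter, gene lists, alternatives and the rule for named genes. The rule took the 10 most positive and 10 most negative genes of each comparison with siNC, the 5 of each sign in siYAP minus siTAZ, and up to 4 members of each list at 2-fold or more. It added up to 10 genes at 2-fold in the same direction in both knockdowns, and WWTR1, YAP1, CCN1, CCN2, ANKRD1, AMOTL2 and AXL whatever their values. It gave 40 genes with a probe set; CCN1 had no named probe set and has no value here. Other list members are named as examples chosen after their values were seen. The alternatives were no filter, a filter at the 75th percentile, a shift of each difference to a median of 0, subtraction of a loess trend (span 0.4), a new quantile normalization, the mean of all probe sets of a gene, and the mean of the control and the other knockdown array as reference. Leaving out genes with identical siTAZ and siYAP values was added after seeing the data.

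The pipeline was tested on simulated data for siTAZ minus siNC with 10768 genes and noise of SD 0.0903. The 2-fold count recovered 100% of 50 genes changed by 3-fold, 62% of 50 changed by exactly 2-fold and 0% of 50 changed by 1.5-fold, and called 0 of 10568 unchanged genes. A list of 20 genes shifted by a constant fell at percentile 0, and 0 of 20 unshifted lists stood apart. At this noise an unchanged gene could hardly reach 2-fold, so the 0 false calls were set in advance. The simulated noise was independent between genes and held no identical values, unlike the deposited table. The outcome therefore checks the code and not the error rate in these arrays. The number of arrays limits the precision of every value. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.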

Results

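The data were 3 microarray profiles of A549 cells, 1 each after transfection of control siRNA, siTAZ and siYAP for 48 h. YAP and TAZ (gene symbols YAP1 and WWTR1) are paralogous transcriptional co-activators that act at the end of the Hippo pathway, mainly through TEAD transcription factors. The series asked which genes depend on TAZ or on YAP in this lung cancer line. Values are RMA levels on a log2 scale. The 3 arrays had similar distributions, with medians of 4.28 (siNC), 4.26 (siTAZ) and 4.27 (siYAP) over all probe sets. There were no replicates, so no value carries an error and no difference was checked against the spread between cultures.

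Each siRNA target was lower in its own array. YAP1 was 8.45 in the control array and 6.87 in the siYAP array, 2.99-fold lower, which left 33.5% of the control level and was the second lowest difference among 10768 kept genes. WWTR1, which encodes TAZ, was 6.50 in the control array and 5.81 in the siTAZ array, 1.61-fold lower, or 62.2% of the control level. It ranked 77 from the lowest among the kept genes. The WWTR1 value in the siYAP array was identical to the control value, and YAP1 in the siTAZ array was 0.21 below it on the log2 scale. A dimmer YAP1 probe set (4.95 in the control array) was 0.57 lower in the siYAP array.

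**Figure D1:**
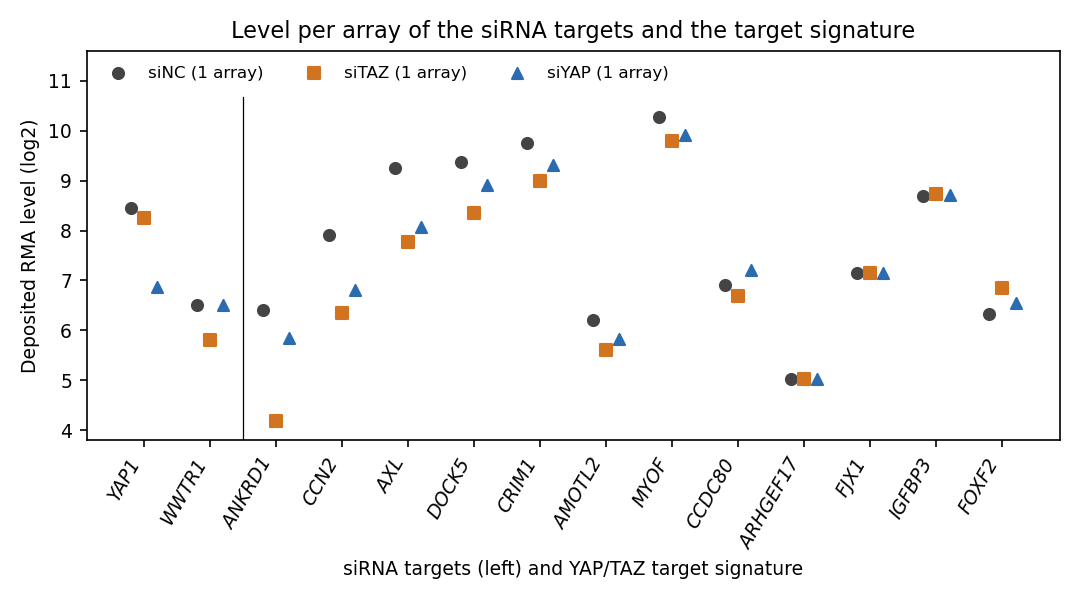
Deposited RMA level (log2, vertical axis) of the siRNA targets YAP1 and WWTR1 and of the 12 kept genes of the YAP/TAZ target signature, with 1 point per array (circle siNC, square siTAZ, triangle siYAP) and no error bars because each group had 1 array. ANKRD1, CCN2, AXL and DOCK5 had their lowest level in the siTAZ array, while YAP1 was lowest in the siYAP array.

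The first comparison asked which genes differed after TAZ knockdown. In the siTAZ array, 26 genes were at least 2-fold lower and 8 at least 2-fold higher than in the control array. The lowest was CCL2, a monocyte-attracting chemokine, which was 7.55-fold lower (9.11 against 6.19). It was followed by ANKRD1, a widely used YAP/TAZ target gene, which was 4.70-fold lower (6.41 against 4.18, a dim level under the filter's 4.27 that leaves the fold uncertain), and by GALNT1, an enzyme that starts mucin-type O-glycosylation, which was 3.18-fold lower. CCN2, a matricellular protein and YAP/TAZ target, was 2.94-fold lower, and AXL, a receptor tyrosine kinase, was 2.76-fold lower. The autophagy receptor gene SQSTM1 was 2.54-fold lower and the protease inhibitor gene TFPI2 was 2.33-fold lower. IFFO2, EIF5A2 and AVL9 were 2.43-fold, 2.37-fold and 2.32-fold lower. Among the genes with higher levels, BMP2, a secreted bone morphogenetic protein, was 2.72-fold higher, the ion channel gene HCN2 2.69-fold and the lysophospholipid acyltransferase gene MBOAT1 2.51-fold. SRM, which encodes spermidine synthase, was 2.13-fold higher and NOC4L, a ribosome biogenesis factor, 2.11-fold. TRANK1 and GXYLT2 were 2.06-fold and 2.01-fold higher. The alarmin gene IL33 (1.98-fold) and KRTAP10-5 (1.95-fold, from a dim control level of 4.27 that leaves the fold uncertain) lay just under the threshold. F8A1 was 2.03-fold higher, but has near-identical copies whose signal the probes may share, as may KRTAP10-5, a member of a multigene family.

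At the lower threshold of 1.5-fold, 110 genes were lower and 82 higher in the siTAZ array. When the mean of the control and siYAP arrays served as the reference, 13 genes were at least 2-fold lower and 1 at least 2-fold higher. CCN2 and TRANK1 were under 2-fold when all their probe sets were averaged (differences of -0.79 and 0.63, where the other CCN2 probe set was very dim, at 1.87 in the control array), and F8A1 after a new quantile normalization.

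Of the 32 gene lists with a percentile, 6 stood apart below and 3 above their matched random lists in the siTAZ comparison. The YAP/TAZ target signature kept 12 of its 22 members, which had a median difference of -0.54 at percentile 0. Of these, 4 were at least 2-fold lower (ANKRD1, CCN2, AXL and DOCK5, the last 2.03-fold lower), 8 were lower by any amount, 2 were higher and 2 had identical values. AMOTL2, an angiomotin family member, was 1.51-fold lower. Further targets lay lower by less, such as CRIM1 (-0.75) and MYOF (-0.48), whereas FOXF2 was 0.53 higher and FJX1 identical. A separate list of 18 other genes described as YAP/TAZ-TEAD targets had a median of -0.067 at percentile 0.03, with TNS3 at -0.77, THBS1 at -0.70 and FGF2 at -0.59, and with ZYX at 0.57.

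The list of inflammatory cytokines and NF-kB targets had a median of -0.12 in the siTAZ array at percentile 0.02, with 9 of its 13 members lower and 1 higher. Its members at 2-fold or more were CCL2 and IL11, a cytokine of the interleukin-6 family, which was 2.15-fold lower. CSF1, a macrophage growth factor, was at -0.70, while PTGS2 (-0.028) and CXCL5 (-0.046) were close to the control. The EGFR ligand and receptor tyrosine kinase list also had a median of -0.12 at percentile 0.02, with EGFR at -0.53 and NRG1, a ligand of the same receptor family, at -0.51. None of its 15 members reached 1.5-fold. The p53 list kept 10 of its 20 genes, and CDKN1A and MDM2 were among those with no named probe set. The 10 kept p53 targets had a median of 0.26 at percentile 100, led by the stress cytokine GDF15 (0.79) and the cyclin CCNG1 (0.57), and TP53INP1 was at -0.36. The 24 DNA replication genes had a median of 0.086 at percentile 99.5, with 15 members higher, 4 lower and 5 identical. The thymidylate synthase gene TYMS was at 0.64 and PCNA at 0.56, while CCNE2 was at -0.31. The 7 kept oxidative phosphorylation genes had a median of 0.22 at percentile 99.8, with UQCRC1, UQCRC2 and CYC1 at 0.32, 0.28 and 0.23. Over the alternatives the oxidative phosphorylation median ranged from 0.12 to 0.23 and that of the p53 targets from 0.15 to 0.28. The extracellular matrix list (median -0.044, percentile 1.64) and the hypoxia and glycolysis list (median -0.043, percentile 1.15) also stood apart below, by medians close to 0. The extracellular matrix call did not hold without the filter on dim probe sets (median 0) or with the stricter filter (median -0.10, larger in size), and this call and that of the DNA replication genes did not hold with the mean of the control and siYAP arrays as reference. The DNA replication and hypoxia calls did not hold when genes with identical siTAZ and siYAP values were left out, although their medians were larger in size (0.12 and -0.088). The inflammatory, EGFR and other YAP/TAZ-TEAD target lists still stood apart with the changed reference, but with medians near 0 (-0.0061, -0.00086 and -0.0043), against -0.48, -0.16 and -0.31 with genes of identical siTAZ and siYAP values left out.

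The second comparison asked which genes differed after YAP knockdown. In the siYAP array, 13 genes were at least 2-fold lower and 8 at least 2-fold higher than in the control array, and at 1.5-fold 41 were lower and 56 higher. CCL2 was again the lowest, at 4.31-fold lower, followed by YAP1 itself. AXL was 2.27-fold lower, and DCP2, which encodes an mRNA-decapping enzyme, 2.26-fold. The adhesion G protein-coupled receptor gene ADGRG6 was 2.22-fold lower, CXCL8, which encodes interleukin-8, 2.16-fold (to a dim level of 4.02, which leaves the fold uncertain) and CCN2 2.13-fold. MMD (2.08-fold), the cell polarity gene PARD6B (2.07-fold) and IL11 (2.01-fold) completed the 10 lowest. ANKRD1 was 1.49-fold lower, AMOTL2 1.30-fold and DOCK5 1.39-fold, all under the threshold. The highest genes were HCN2 at 2.99-fold, BMP2 at 2.74-fold and the long non-coding RNA LINC01433 at 2.34-fold. NOC4L was 2.23-fold higher, EIF4EBP2, a repressor of cap-dependent translation, 2.20-fold, and MARVELD1 2.06-fold. TRANK1 and SRM were 2.06-fold and 2.03-fold higher. TRIM31 (1.99-fold), which had 5 probe sets with differences of 0.94 to 1.02, and KRTAP10-5 (1.97-fold, again uncertain for its dim control level) lay just under the threshold.

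With the mean of the control and siTAZ arrays as the reference, 1 gene was at least 2-fold lower and 0 were at least 2-fold higher in the siYAP array. CCN2 and TRANK1 were again under 2-fold when all their probe sets were averaged (-0.55 and 0.58).

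In the siYAP comparison 7 lists stood apart below and 3 above. The YAP/TAZ target signature had a median of -0.37 at percentile 0, with 2 of 12 members at least 2-fold lower (AXL and CCN2), 7 lower by any amount and 3 higher. CRIM1 was at -0.44 and MYOF at -0.36, while CCDC80 was at 0.30. Against the mean of the control and siTAZ arrays the signature's median was -0.021, inside the bounds of its random lists. The inflammatory list had a median of -0.19 at percentile 0, with 3 members at least 2-fold lower (CCL2, CXCL8 and IL11) and 0 at least 1.5-fold higher. Its median ranged from -0.35 to -0.082 over the alternatives. The EGFR ligand and receptor list had a median of -0.12 at percentile 0 (-0.17 to -0.050 over the alternatives), with the ligand gene EREG at -0.57 and MET at -0.26. The p53 targets (median 0.13, percentile 99.9), the DNA replication genes (0.11, percentile 99.97) and the oxidative phosphorylation genes (0.18, percentile 99.8) stood apart above. Over the alternatives the DNA replication median ranged from 0.033 to 0.19. The other YAP/TAZ-TEAD targets (-0.024), the Hippo pathway components (-0.018), the extracellular matrix list (-0.024) and the RNA interference list (-0.061) stood apart below by small medians. YAP1 is itself a member of the Hippo list. The calls of the p53, oxidative phosphorylation, extracellular matrix, Hippo, RNA interference and other YAP/TAZ-TEAD target lists were lost with the mean of the control and siTAZ arrays as reference. Without the filter or with a stricter one, the extracellular matrix (medians 0 and -0.080) and RNA interference calls were also lost, as was the latter with the mean of all probe sets, although its median stayed at -0.061 in each of these, and the Hippo and oxidative phosphorylation calls were lost when genes with identical siTAZ and siYAP values were left out, where the Hippo median was larger in size and the oxidative phosphorylation median smaller, without reaching 0.

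**Figure D2:**
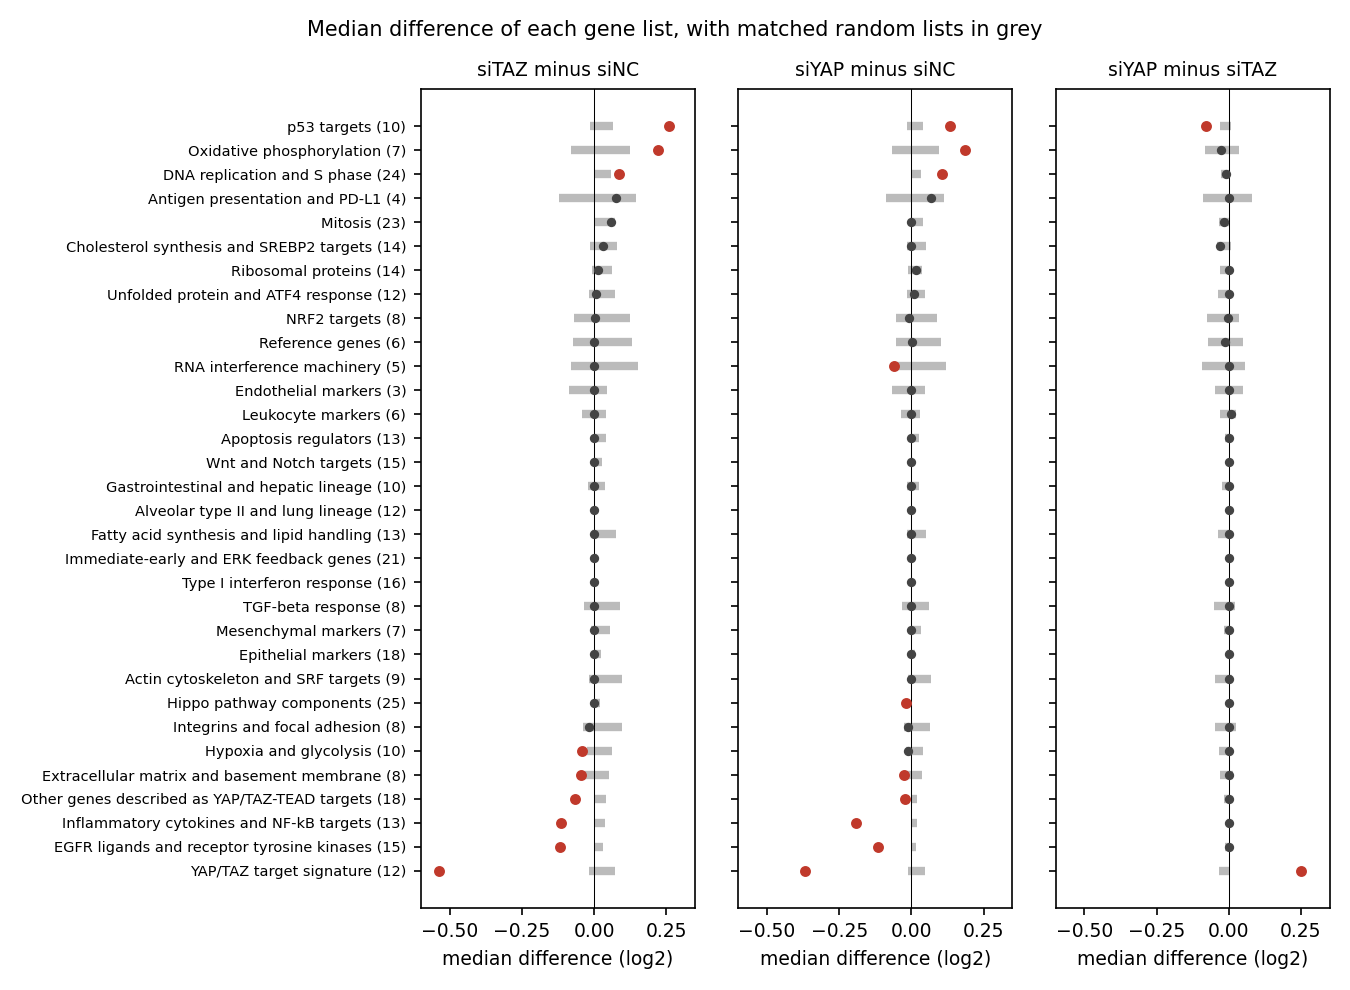
Median log2 difference (horizontal axis) of each of 32 gene lists, with the number of kept members in brackets, in the 3 comparisons. Grey bars span the percentile bounds of 10000 random lists matched on size and level, and red points lie at or beyond those bounds; the YAP/TAZ target signature lies at -0.54, -0.37 and 0.25.

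Many lists did not stand apart in either comparison with the control. The 16 type I interferon response genes, a set often checked after siRNA transfection, had a median of 0 in both, with IFIH1, an RNA sensor, at 0.68 and 0.62 and ISG15 at -0.14 in both. The 23 mitosis genes had medians of 0.058 and 0, with PLK1 at 0.63 and 0.46. FOXM1, a transcription factor of the mitotic programme, was at -0.65 in the siTAZ array and 0.073 in the siYAP array. Medians were 0 in both comparisons for the 18 epithelial markers, the 7 mesenchymal markers and the 12 alveolar and lung lineage genes. PD-L1 (CD274) was at 0.15 in both, at a dim level of 4.93 in the control array. Among markers of other cell types, the 6 leukocyte and 3 endothelial markers had medians of 0, with most members identical in the siTAZ and control arrays, while the leukocyte marker CD68 was at 0.57 and 0.59. Of the kept fibroblast markers, LUM was at 0.69 and 0.66 and THY1 at -0.16 in both. The antigen presentation list had medians of 0.076 and 0.069 and did not stand apart. Nor did the integrin and focal adhesion, actin, TGF-beta, immediate-early, NRF2, cholesterol, fatty acid, unfolded protein, gastrointestinal lineage, Wnt and Notch, apoptosis or ribosomal protein lists. Some of these lists were measured only in part. The integrin and focal adhesion list kept 8 of 24 genes and no integrin subunit gene. The antigen presentation list kept 4 of 17 and no HLA gene, and the NRF2 list kept 8 of 22. Members with no named probe set have no value here. Under at least 1 alternative, however, the immediate-early and the Wnt and Notch lists stood apart below in both comparisons, the epithelial and mesenchymal lists below in the siTAZ comparison, and the mitosis and gastrointestinal lineage lists above in the siTAZ comparison. The immediate-early list stayed within its bounds in only 4 of 8 alternatives for siTAZ and 5 of 8 for siYAP, and its medians reached -0.13 and -0.20. It had 10 members lower and 2 higher in the siTAZ array, and 9 lower and 3 higher in the siYAP array. The 6 reference genes had medians of 0.00 in both, with TBP at 0.28 and 0.23. GAPDH was identical in the siTAZ and control arrays and 0.0042 higher in the siYAP array. In the control array GAPDH, PPIA and EEF1A1 had lower levels than TBP, while HPRT1 and PGK1 had higher ones. EEF1A1 also lay below the median of the kept genes. Whether these probe sets report the main transcripts of their genes was not tested, so their small differences are not evidence of stable reference genes.

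The third comparison set the knockdowns beside each other. Of the genes at 2-fold, 7 were lower and 5 higher in both arrays, and 0 went in opposite directions. The genes lower in both were CCL2, AXL, CCN2, IL11, PARD6B, MMD and MIR4454, a microRNA gene named here after its value was seen and just past 2-fold in both. Those higher in both were BMP2, HCN2, NOC4L, SRM and TRANK1, of which TRANK1 had identical values in the siTAZ and siYAP arrays. Independent lists of these sizes would share 0.0314 lower and 0.00594 higher genes, and simulated unchanged arrays that shared a control gave 0 of each, an outcome set by the small size of the simulated noise. Across the 10768 genes, which are not independent replicates, the siTAZ and siYAP differences had a Pearson r of 0.71 and a Spearman rho of 0.63, against an r of 0.50 in the simulation with normal noise and of 0.51 to 0.58 in simulated unchanged arrays summarised by median polish. The covariance was 0.0184, against 0.00813 in the simulation. With 1 control array the covariance could not be split, so part or all of the excess may come from the shared control.

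**Figure D3:**
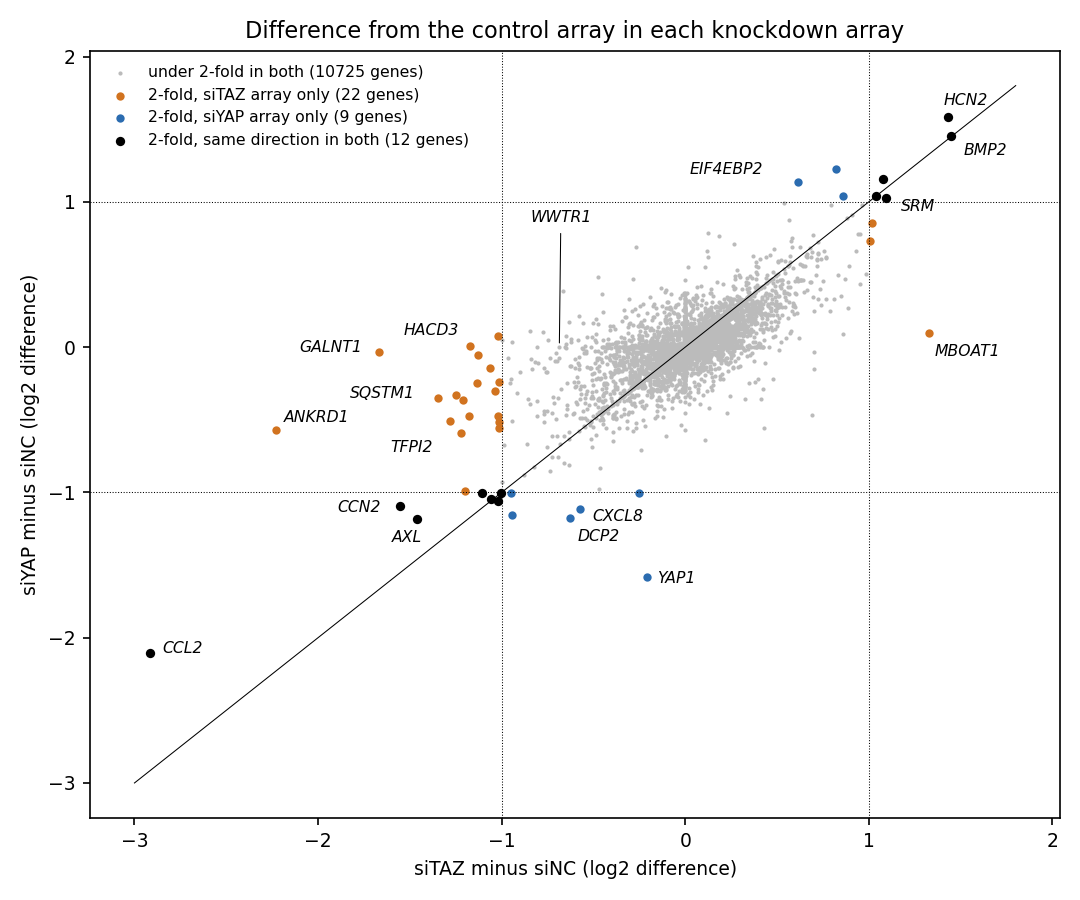
Log2 difference from the control array after siTAZ (horizontal axis) and siYAP (vertical axis) for the 10768 kept genes, 1 point per gene, with dotted lines at 2-fold and a solid line where both are equal. CCL2, CCN2, AXL, BMP2 and HCN2 differed in both arrays, ANKRD1, GALNT1 and SQSTM1 reached 2-fold in the siTAZ array and not in the siYAP array, and YAP1 reached it only in the siYAP array.

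The direct difference, siYAP minus siTAZ, does not subtract the control array, although all 3 arrays were summarised together. Here 7 genes were at least 2-fold higher and 3 at least 2-fold lower in the siYAP array. ANKRD1 was 3.16-fold higher in the siYAP array, a fold taken against its dim siTAZ level of 4.18 and so uncertain, GALNT1 3.11-fold, HACD3, an enzyme of very long-chain fatty acid synthesis, 2.27-fold and CPNE3 2.13-fold. HNRNPA1P33 was 2.10-fold higher, but is a pseudogene whose probes may take signal from its parent gene. YAP1 was 2.59-fold lower in the siYAP array, MBOAT1 2.34-fold, the ceramidase gene ACER2 2.22-fold, TCTN2 1.98-fold and NUDT11 1.8-fold (to a dim level of 4.68). The YAP1 difference was under 2-fold (-0.87) when its probe sets were averaged. Of the 26 genes at least 2-fold lower in the siTAZ array, 24 were also below the control in the siYAP array, 9 of them by at least 1.5-fold, and 16 were at least 1.5-fold lower in the siTAZ than in the siYAP array. Of the 13 genes at least 2-fold lower in the siYAP array, 10 were at least 1.5-fold lower in the siTAZ array, and 1, YAP1, was at least 2-fold below the siTAZ array too. The counts against the control use the shared control array, so some agreement arises without any knockdown effect. The 26 genes were picked for a low siTAZ value and the 13 for a low siYAP value. Values nearer the control in the other array, as in the count of 16, therefore arise in part from that choice. Among the 4444 kept genes with both differences not 0, 85.1% had the same sign, against 66.7% in simulated unchanged arrays. These shares are not alike, because the simulation held no identical values. Of the 4444 genes, 1377 had identical siTAZ and siYAP values apart from the control, which share a sign by construction. How much of the gap comes from such genes was not tested. The 24 also include values near 0, such as GALNT1 at -0.034. The YAP/TAZ target signature was higher in the siYAP than in the siTAZ array (median 0.25, percentile 100), with 8 members higher, 2 lower and 2 identical. The p53 targets were lower in the siYAP array (median -0.079, percentile 0.26). The DNA replication, oxidative phosphorylation, inflammatory and EGFR lists did not stand apart in this comparison. With the stricter filter the EGFR, epithelial and Wnt and Notch lists stood apart above, as did the mesenchymal list with the mean of all probe sets, and the mitosis and alveolar lists stood apart below when genes with identical siTAZ and siYAP values were left out.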

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

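The tests of a copied column, of array noise, of the control array and of a trend were chosen after the result was seen, unlike the median polish simulation, the check of shared dim values and the count bearing on off-target action. Of the named genes, 5 lay on opposite sides of the control in the knockdown arrays. With 1 array per group this difference was not tested. ACER2 was 0.69 above the control in the siTAZ array and 0.46 below it in the siYAP array (siYAP minus siTAZ -1.15). TCTN2 lay at 0.43 and -0.56 (-0.99) and NUDT11 at 0.70 and -0.15 (-0.85). CPNE3 lay at -1.02 and 0.076 (1.09) and HACD3 at -1.17 and 0.0088 (1.18), so their siYAP values were close to the control, and that of HACD3 changed sign after a new quantile normalization (-0.0048). Among the probe sets without a gene name, which no comparison used, 68 were at least 2-fold higher in the siTAZ array and 69 in the siYAP array than in the control array, out of 15272 at or above the level filter, and 102 and 58 were at least 2-fold lower. This made 1.11% and 0.832% of them at 2-fold, against 0.316% and 0.195% of the kept genes with a name. In siYAP minus siTAZ, which does not subtract the control array, the shares were 0.818% and 0.0929%. The shares are of unlike sets: each unnamed probe set counted on its own, while a named gene counted by its brightest probe set.

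Most probe sets, 53.5% for siTAZ and siNC, 55.1% for siYAP and siNC and 56.8% for siYAP and siTAZ, had identical values to all deposited decimals in a pair of arrays. A copied column is argued against by the 43.2% of probe sets that differ in the closest pair. A candidate explanation is the median polish of RMA over 3 arrays: when simulated probe sets of noise alone were summarised this way, 30.1% were identical in a pair with 5 probes per set and 84.1% with 25 probes, while a true log2 shift of 1 in 1 array left 0% identical to the first array and was estimated at 0.87 to 0.92. A coarse ladder of dim signals stays open beside it: up to 602 probe sets shared 1 value on the control array, and among probe sets with a value of their own the identical share was 15.7%, between the bounds set for and against. Either way, small differences in this table may have been set to 0, so a value of 0 is not evidence that a gene did not change. In the median polish simulation a true log2 shift of 0.5 was estimated at 0.36 to 0.40, and a shift of 0.1 at 0 to 0.0026. If the polish acted in this way here, differences near 1.5-fold, such as that of WWTR1 in the siTAZ array, may be understated.

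The siTAZ and siYAP differences overlapped, and 39 genes (Poisson 95% limits 27.7 to 53.3) were at least 1.5-fold apart in the control array while the knockdown arrays lay within 0.1 of each other, among them BMP2, SRM, NOC4L, PARD6B and MMD. For these named genes, array noise of equal size is argued against by the 0 genes apart in the siYAP array alone (upper limit 3.69, with genes taken as independent), with 28 in the siTAZ array alone. YAP1 is not in that siYAP count, because it lay 0.21 below the control in the siTAZ array, outside the 0.1. Array noise of equal size stays open for the unnamed probe sets. There 80 stood apart in the control array alone (limits 63.4 to 99.6), 74 in the siTAZ array alone (58.1 to 92.9) and 44 in the siYAP array alone (32.0 to 59.1). Over all probe sets, unfiltered, some had identical values in 2 arrays and were at least 1.5-fold apart in the other. These were 26 higher and 24 lower for siNC, 21 and 19 for siTAZ, and 19 and 18 for siYAP. A deviation of the control array stays open too, both for the YAP/TAZ target signature, whose median lay at percentile 0 in both comparisons, and for the 10381 genes outside the lists, whose covariance was 2.16 times that of unchanged arrays. Both comparisons share that array, so a shared effect of the knockdowns and a peculiarity of that culture or hybridisation cannot be told apart.

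In the siTAZ array alone, with siNC and siYAP within 0.1 of each other, 24 genes were at least 1.5-fold lower and 4 at least 1.5-fold higher, and at 2-fold 4 were lower (GALNT1, HACD3, HNRNPA1P33 and CPNE3) and 1 higher (MBOAT1). WWTR1 itself was among the 24. The average intensity-dependent trend left between the normalized arrays reached at most 0.021 on the log2 scale, too small to carry a 1.5-fold difference. Quantile normalization had already removed most of any such trend, so this check could hardly come out otherwise. Off-target action of the siRNA, which would lower transcripts that match its seed, stays open for these genes other than WWTR1 because no seed was searched: the siRNA sequence and 3' UTR sequences were not used here. An effect particular to TAZ stays open as well, and was not tested.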

How the results depend on the processing

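Every difference rests on 1 array per group, and a gene's own error is unknown; the alternatives show only how the processing moves the values. The shift to a median difference of 0 moved nothing, because the median was already 0. Of 51 differences of named genes at 2-fold or more, 45 stayed past it in every alternative run for single genes, which leaves out the changed reference, and 0 of the 350 values changed direction; the 6 values that dropped below were those of CCN2, TRANK1, F8A1 and YAP1 (siYAP minus siTAZ) given above. The difference of WWTR1 in the siTAZ array was -0.69 throughout and that of YAP1 in the siYAP array ranged from -1.59 to -1.08. Genes at 2-fold in both knockdowns ranged from 6 to 8 lower and from 4 to 5 higher, and the correlation of the differences from 0.67 to 0.72. Of 21 list calls, 11 held in every alternative and 0 changed direction. Without the filter on dim probe sets, siYAP minus siTAZ gave 5 genes at least 2-fold lower and 32 at least 1.5-fold lower. The lists above their random lists in that comparison numbered 4 with the stricter filter and 2 with the mean of all probe sets; with genes of identical siTAZ and siYAP values left out, an alternative chosen after seeing the data, 3 lay below and 2 above. The mean of the control and the other knockdown as reference shrinks by construction any difference the knockdowns share. It gave 13 genes lower and 1 higher for siTAZ, 1 lower and 0 higher for siYAP, and for siYAP 2 lists below, 1 list above and a signature median of -0.021. The stricter filter, or leaving out identical values, gave no value for some named genes, such as ANKRD1 and TRANK1, or for lists left with under 3 members. No paired analysis was possible because each group has 1 array.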

Other observations

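The genes named here are on none of the gene lists; they were picked after their values were seen and have no replicate. The protease-activated receptor gene F2RL2 was at -1.20 in the siTAZ array and -0.99 in the siYAP array, the oxytocin receptor gene OXTR at -0.99 and -0.67, and ROR1, a receptor tyrosine kinase-like protein, at -0.86 and -0.67. The transcription factor gene ETS1 was at -0.69 and -0.75. WLS, which carries Wnt proteins to the cell surface, was at 0.95 and 0.78, and the atypical MAP kinase gene MAPK4 at 0.88 and 0.89.

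Other genes were lower by more in the siTAZ array than in the siYAP array, which was not tested. OSMR, which encodes the oncostatin M receptor, was at -1.02 in the siTAZ array and -0.24 in the siYAP array, PBRM1, a chromatin remodelling subunit, at -0.96 and -0.25, and the mitotic kinesin gene KIF4A, which has the close copy KIF4B and is uncertain, at -0.94 and 0.033. CTPS1, which encodes a CTP synthase, was lower by just over 2-fold in the siYAP array and at -0.25 in the siTAZ array.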
